A study of Mus musculus with 4 samples.

How the data were processed

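Nuclei of the dorsal lateral geniculate nucleus (dLGN), the part of the thalamus that relays retinal input to visual cortex, were profiled by single-nucleus RNA sequencing in male mice at postnatal day 20. There were 4 libraries: 2 from wild-type mice (WT, replicates A and C) and 2 from littermates carrying the MeCP2 QKI knock-in allele (QKI, replicates B and D). Per the labels, each library pooled tissue of 3 mice, so that 6 mice stood behind each genotype and a replicate here is a pool of mice, not a single animal. The labels name no batch, day of collection or lane shared between libraries, and replicate letters were not shared between genotypes, so libraries were not paired.

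Per the labels, nuclei were released by douncing in detergent, purified over an iodixanol gradient, and up to 10000 were loaded per lane of a 10x Genomics 3' v3.1 kit, which captures polyadenylated RNA near its 3' end. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, not scaled or transformed. Per the file headers they were written by Cell Ranger 7.0.0, whereas the submitters' processing notes name bcl2fastq, Cell Ranger 3.0.0, Seurat 3 and the genome build mm10. Whether reads in introns were counted and which annotation release was used are not given in the sources used here. Counting introns raises the counts of long genes, and a 3' kit says little about splice forms or about the codons a knock-in changes. The matrices list 31058 features, of which 5 are viral sequences with 0 UMIs. Gene positions and lengths came from GENCODE M21 on mm10 (GRCm38), which held 31011 of the 31058 features by gene identifier, 30541 of them under the same symbol. Genes that overlap or run antisense to each other may share reads, so their counts are less certain.

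The libraries held 6103 (WT A), 8413 (WT C), 9913 (QKI B) and 11134 (QKI D) barcodes and 36291694, 29812434, 39678201 and 45110956 UMIs. The barcodes of QKI D exceed the 10000 nuclei that the labels give as the most loaded, and the sources used here do not say why. The barcodes had already been filtered, since the smallest total of any barcode was 500 to 502 UMIs, so empty droplets could not be examined and free RNA was not subtracted. Barcodes with under 500 genes (49, 159, 167 and 178) or at least 5% mitochondrial UMIs (2, 2, 8 and 9) were removed. Scrublet scored doublets in each library, and the highest-scoring 0.8% per 1000 barcodes were removed (295, 555, 772 and 975). There remained 5757, 7697, 8966 and 9972 nuclei with medians of 4259, 2433, 2900 and 2830 UMIs. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were chosen with library as the batch key, and 30 principal components, 15 neighbours and Leiden resolution 1.0 gave the clusters, with no integration across libraries. A cluster took the name of a cell type when at least 3 of its markers were at least 2-fold over the median cluster at 5 or more CPM (counts scaled to each profile's total), with 10 CPM added before logarithms. Glial clusters with a relay neuron score above 1.0 on the log2 scale were left unnamed, a limit set after the clusters had been seen.

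UMIs were summed per library within relay neurons, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and endothelial cells, each of which held at least 30 nuclei in every library, and within all nuclei together. Summed counts ranged over the libraries from 18825117 to 23136566 in relay neurons, 1711627 to 2665381 in inhibitory neurons, 1568728 to 2949001 in astrocytes, 2630242 to 4797277 in oligodendrocytes, 642064 to 1328865 in oligodendrocyte precursors, 223721 to 420256 in microglia and 807383 to 1854802 in endothelial cells. Genes were tested with the edgeR quasi-likelihood test (robust, TMM scaling, filterByExpr) for QKI against WT, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The p-values describe differences beyond the spread between 2 pools per genotype. Lists were tested with camera at its preset correlation of 0.01 when at least 5 members were tested, and again with camera at an estimated correlation and with fry. An interaction model with library as a block asked whether a genotype difference in relay neurons departed from that in each other class. Shares of nuclei were compared by exact permutation of libraries, whose smallest possible p with 2 against 2 is 0.333. Long genes were those of at least 100 kb.

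In total 36 lists were set out, of which 34 had enough tested members in at least 1 class; markers of habenular neurons and of ependymal or choroid plexus cells did not. Genes are named by rule. In relay neurons the 5 of lowest p in each direction are named, and in every other class the 2 of lowest p. Up to 4 members of lowest p are named from each list that passed camera or that the study's question asks about, namely immediate early genes, late response genes, synapse refinement genes and MeCP2 partners. The comparisons, lists, naming rule and the following further analyses were chosen before the data were examined: DESeq2, RLE scaling, no low-count filter, leaving out each library in turn, no doublet removal, at least 1000 genes per nucleus, thinning to equal totals, the largest relay cluster alone, Leiden resolutions 0.5 and 2.0, the other list tests, and other limits for long genes and mean counts. Fits without the shallowest relay cluster, without a cluster of endothelial cells that also carried mural markers, and with a term for A and B against C and D were added after the data had been seen. Leaving out a library leaves a lone library in its group, which is then assumed to vary as the other group does.

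The analysis was tested on simulated counts, drawn for each gene independently from its mean, the library totals and its fitted spread. Changed genes had a mean count of at least 50, and no grouping of libraries other than genotype was simulated. With 50 genes changed at each of 1.25-, 1.5-, 2- and 3-fold, 14%, 66%, 92% and 100% were recovered in relay neurons, with 35 false calls beside 136 true ones, and 9 genes were called where nothing had been changed. Recovery at 2-fold was 92% in inhibitory neurons, 82% in astrocytes, 86% in oligodendrocytes, 90% in precursors, 80% in microglia and 14% in endothelial cells. These figures do not cover genes with a mean count under 50. In microglia 505 of the 6953 genes tested had a mean count of at least 100. Lists of 20 genes shifted 1.2-fold gave camera p between 1.81e-14 and 7.45e-06, and unshifted lists between 0.0734 and 0.830. Since simulated genes varied independently, these values cannot show how camera at its preset correlation behaves when members vary together. In the measured data the 95% confidence interval of the fold change lay within 1.5-fold in either direction for 94.9% of the 11281 relay genes with a mean count of at least 100. That figure was 91.6% in inhibitory neurons, 87.6% in astrocytes, 90.3% in oligodendrocytes, 92.3% in precursors, 75.8% in microglia and 68.8% in endothelial cells.

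Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Reads, splice forms, phosphorylation of MeCP2 and chromatin were not analysed here. Gene tests had not been planned for mural cells, fibroblasts, macrophages or unnamed clusters, and of these the shares alone were compared. A fit of newly formed oligodendrocytes was added after the data had been seen.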

Results

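The series concerns MeCP2, a protein that binds methylated DNA and is phosphorylated when neurons are active, and the refinement of synapses from retina to thalamus. In the dLGN at postnatal day 20 no gene passed between QKI and WT libraries within a cell class, Mecp2 lay at nearly the same level, and a lone gene, Mgat5b, passed a comparison between classes. Among lists of genes 67 of 234 list and class pairs passed camera, mitochondrially encoded genes and endothelial markers among them. None passed with an estimated correlation (lowest adjusted p = 0.587) or with fry (lowest adjusted p = 0.133), and the p given below for an estimated correlation are not adjusted. Most list calls depended on which library was left out.

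Excitatory relay neurons, the cells that receive retinal synapses, were the largest class, with 37.97%, 50.23%, 43.21% and 35.84% of nuclei in WT A, WT C, QKI B and QKI D (2186, 3866, 3874 and 3574 nuclei). Their mean share was 44.1 ± 8.67% in WT and 39.5 ± 5.21% in QKI (mean ± SD, n = 2 pools per genotype; exact p = 0.667). Astrocytes made up 16.17%, 11.36%, 15.57% and 16.71%, oligodendrocytes 14.63%, 12.38%, 11.84% and 16.96%, and oligodendrocyte precursors 9.484%, 5.353%, 7.172% and 7.952%, with exact p = 0.667, 1 and 1. Newly formed oligodendrocytes held 6.705%, 5.34%, 5.911% and 6.799% (exact p = 0.667), inhibitory neurons 5.194%, 6.535%, 7.372% and 5.144% (exact p = 1), and microglia 5.385%, 3.131%, 3.201% and 4.302% (exact p = 1). Cluster 15, counted as newly formed oligodendrocytes, scored nearly as high for oligodendrocytes (2.71 against 2.68). At resolution 0.5 newly formed oligodendrocytes held 4.186%, 3.365%, 3.837% and 5.084%. Endothelial cells lay higher in both QKI libraries (3.948% and 4.874%) than in both WT libraries (3.387% and 3.742%), and so did fibroblasts (0.8923% and 0.9727% against 0.608% and 0.4417%). Each of these reached exact p = 0.333, the lowest that 4 libraries can give. The fibroblast difference of 0.408 percentage points shrank to 0.0953 (exact p = 1) among nuclei with at least 1000 genes. With a library left out, the share of nuclei per class moved most in relay neurons, from a difference of −4.58 points to −10.7 without WT A and to 1.56 without WT C, and it was −1.22 among nuclei with at least 1000 genes.

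**Figure D1:**
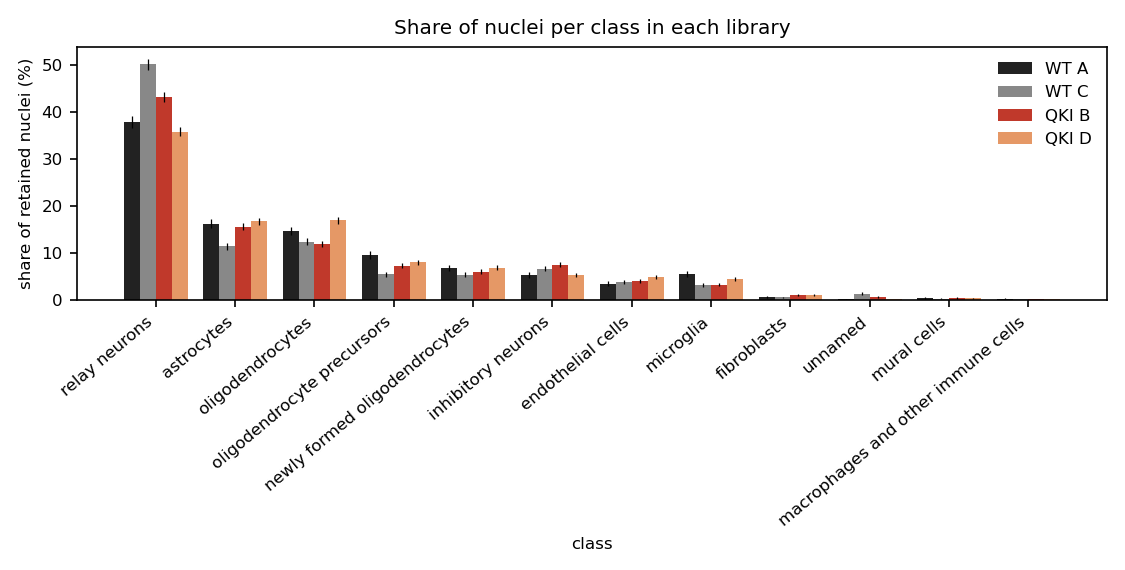
Share of nuclei in each cell class, for each of the 4 libraries. Bars show the percentage of a library's retained nuclei, and lines the 95% binomial interval.

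Relay neurons formed 3 clusters that the libraries filled unevenly. Cluster 14, the largest (median 7523 UMIs), held 1341, 1167, 1789 and 1476 nuclei of WT A, WT C, QKI B and QKI D, and cluster 10 (median 6959 UMIs) held 594, 735, 835 and 871. Cluster 5, the shallowest (median 2750 UMIs), held 251, 1964, 1250 and 1227, and thus most relay nuclei of WT C but few of WT A. Median UMIs per relay nucleus were 8834, 4264, 5660 and 5883. The summed profiles below therefore mix these clusters in different proportions.

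Mecp2 itself lay at nearly the same level in both genotypes. In relay neurons it measured 56.9 ± 0.00324 CPM in WT and 54.9 ± 1.42 CPM in QKI (n = 2 each), a log2 fold change of −0.05 (SE 0.07, 95% interval −0.21 to 0.10). The log2 fold changes elsewhere were 0.01 (SE 0.15) in inhibitory neurons, 0.06 (SE 0.14) in astrocytes, −0.13 (SE 0.14) in oligodendrocytes, 0.23 (SE 0.19) in precursors, −0.02 (SE 0.26) in microglia and 0.01 (SE 0.15) in endothelial cells. Relative to each class's total UMIs, Mecp2 was highest in microglia and endothelial cells, with 131 and 129 CPM in WT. The microglial value rests on 51 and 23 UMIs in 310 and 241 nuclei of WT A and WT C. Relay neurons held 1168 and 1084 UMIs in 2186 and 3866 nuclei, so per nucleus microglia carried less. A knock-in that changes codons need not alter transcript level, so these values say nothing about whether the genotype labels hold.

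In relay neurons no gene passed the test between genotypes. The lowest p-values among genes higher in QKI belonged to Syndig1, which encodes a synaptic membrane protein that binds AMPA receptors (114 ± 0.264 CPM in WT, 147 ± 6.65 in QKI, log2 fold change 0.36, SE 0.07), and Cnih3, an auxiliary subunit of AMPA receptors (31.7 ± 4.68 and 45.5 ± 5.97 CPM, 0.52, SE 0.12). Beside them stood the orphan receptor Gpr162 (32.5 ± 6.04 and 46.1 ± 0.982 CPM, 0.51, SE 0.11), the volume-regulated anion channel subunit Lrrc8c (50.1 ± 2.82 and 62.2 ± 2.55 CPM, 0.31, SE 0.08) and the protein disulfide isomerase Pdia3 (56.1 ± 4.34 and 69.8 ± 2.68 CPM, 0.31, SE 0.08). Lower in QKI were Igsf21, a synaptic adhesion protein (52.3 ± 1.29 and 41.0 ± 2.18 CPM, −0.35, SE 0.08), Lrrc40 (166 ± 7.41 and 137 ± 6.73 CPM, −0.28, SE 0.07), and the predicted genes Gm26573 (−0.35, SE 0.09), Gm9573 (−1.53, SE 0.41) and Gm48239 (−0.24, SE 0.07). On mm10 these genes lie at chromosome 2:149829211–150004392 (Syndig1), 1:181352628–181460641 (Cnih3), 6:124858444–124863983 (Gpr162), 5:105519388–105613018 (Lrrc8c), 2:121413775–121438687 (Pdia3), 4:140026846–140246784 (Igsf21) and 3:158036662–158068487 (Lrrc40).

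The edgeR quasi-likelihood test called 0 of 17124 relay genes, 396 had an unadjusted p under 0.05, and DESeq2 called 0, with 85 under 0.05. Those 396 genes are 2.31% of the genes tested, where 5% would be expected if no gene differed. Syndig1, Igsf21 and the others named above did not pass, and the lowest Benjamini-Hochberg adjusted p of that test in relay neurons was 0.99992. With a term for A and B against C and D, added after the data had been seen, the edgeR quasi-likelihood test called 16 relay genes, among them Cnih3 and Gpr162 (Benjamini-Hochberg adjusted p = 7.8e-06 each), Syndig1 (0.00682), Igsf21 (0.0246), Gm26573 (0.0338) and Pdia3 (0.0472). The same fit called 16 genes in simulated data with no change and 24 for A and D against B and C, so these calls are not taken as differences between genotypes. In 28.4% of relay genes both QKI libraries lay on the same side of both WT libraries, against 33.3% by chance. Without WT A, WT C, QKI B or QKI D the same test called 76, 184, 0 and 3 relay genes, so counts depended on which pool was left out.

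**Figure D2:**
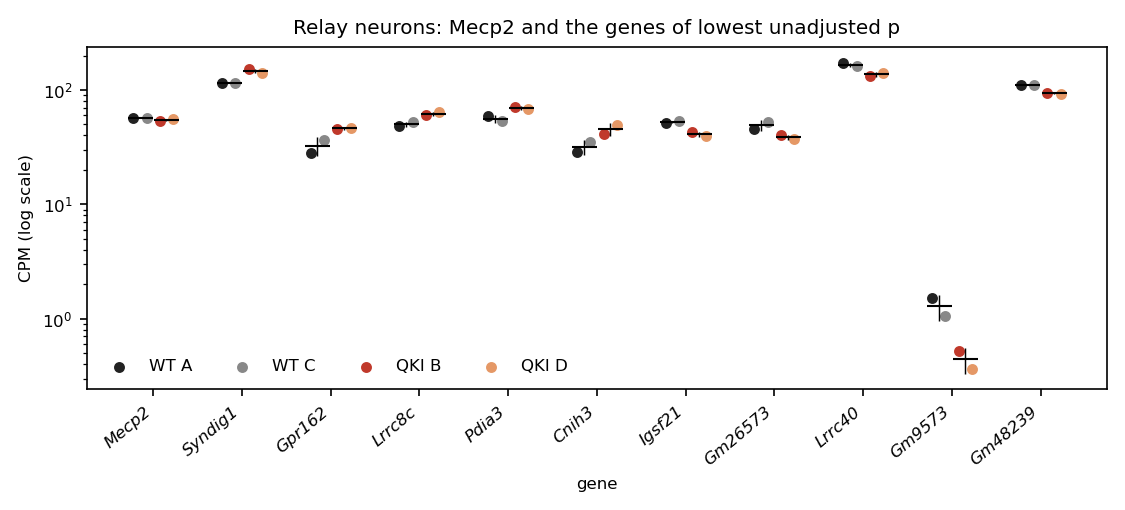
Expression of Mecp2 and of the 10 relay neuron genes with the lowest p-values, 5 in each direction, in CPM on a logarithmic axis. Points are the 4 libraries, and lines give the mean and standard deviation of each genotype.

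Genes that neuronal activity induces did not pass as groups in relay neurons. Immediate early genes, the first genes transcribed after activity, had a median log2 fold change of −0.16 with 4 of 17 members positive (camera adjusted p = 0.138), among them Nr4a2 at −0.71, Fosl2 at −0.62, Ier2 at −0.29 and Klf4 at 0.35. Late response genes, the secreted and synaptic products that follow, had a median of 0.11 with 14 of 21 positive (camera adjusted p = 0.134), including Tnfrsf12a at 0.32, Homer1 at 0.15, Scg2 at 0.15 and Inhba at −1.19. Synapse refinement genes had a median of 0.00 with 10 of 20 positive (camera adjusted p = 0.138), with Sema7a at 0.20, B2m at 0.48 and the complement gene C1qa at 0.97. Their mean was 0.05 and the test pointed up, so median and test differed in sign. MeCP2 partners and the DNA methylation machinery also had a median of 0.00, with 12 of 25 positive (camera adjusted p = 0.996), among them the methyltransferase Dnmt3b at 0.59, Mbd3 at 0.21, Mbd1 at −0.13 and the demethylase Tet3 at −0.10. Adjusted over the list alone, 0 relay genes passed in any list, as over all genes tested.

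In relay neurons 4 of 33 lists passed camera, each upwards in QKI, and none of the 4 is a list of neuronal genes. Markers of endothelial cells rose (median 0.38, 8 of 8 positive, camera adjusted p = 5.27e-08; p = 0.113 with an estimated correlation), with Ly6c1 at 0.66, Slco1a4 at 0.46, Itm2a at 0.40 and Flt1 at 0.32. Mitochondrially encoded genes rose (median 0.28, 12 of 13 positive, camera adjusted p = 0.0276; p = 0.455 with an estimated correlation), with mt-Nd4l at 0.39, mt-Atp8 at 0.38, mt-Co1 at 0.36 and mt-Nd4 at 0.28. Markers of astrocytes (median 0.13, 8 of 11 positive, camera adjusted p = 0.0435) and perisynaptic astrocyte genes (median 0.09, 13 of 19 positive, camera adjusted p = 0.0265) rose as well, with p = 0.443 and p = 0.380 at an estimated correlation. Their members included the connexins Gjb6 (0.94) and Gja1 (0.29), the glutamate transporter Slc1a2 (0.09), Sparc (0.48), Agt (0.48), Gpc6 (0.12) and Aqp4 (0.33).

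Per library, the relay medians of mitochondrially encoded genes relative to the WT mean were −0.17, 0.17, −0.13 and 0.58, and those of endothelial markers −0.09, 0.09, 0.20 and 0.54, so QKI D stood above the others on both lists. Flt1 itself measured 8.53, 9.51, 10.2 and 12.3 CPM in WT A, WT C, QKI B and QKI D. Without QKI D the mitochondrial median turned to −0.16, endothelial markers stood at 0.21 without a call, and markers of astrocytes and perisynaptic genes lost theirs at 0.12 and −0.01. Without WT A the medians were 0.16, 0.32, −0.12 and −0.07 for mitochondrial genes, endothelial markers, astrocyte markers and perisynaptic genes, of which endothelial markers alone kept their call, and without WT C or QKI B every call held. With no low-count filter endothelial markers alone kept their call, and the other 3 lists lost theirs. In the fit without the shallowest relay cluster, added after the data had been seen, all 4 calls held and further relay lists passed camera.

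**Figure D3:**
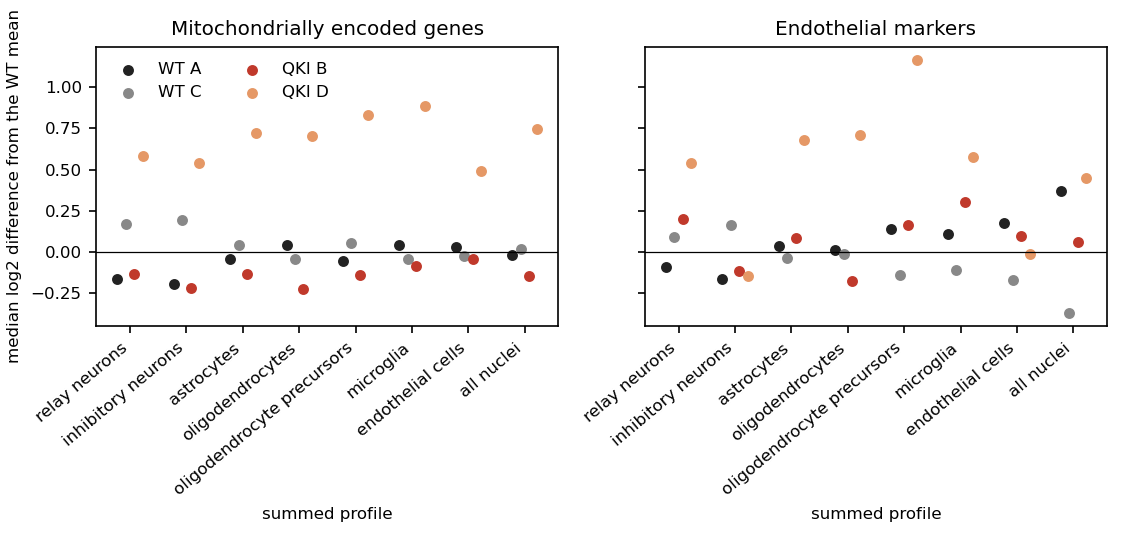
Median log2 difference from the WT mean, per library, for mitochondrially encoded genes and for markers of endothelial cells, in 7 cell classes and in all nuclei. Points are the 4 libraries.

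No list of neuronal gene families passed in relay neurons, though glutamate receptor and presynaptic vesicle genes came near. Glutamate receptor genes had a median of 0.02 (camera adjusted p = 0.0944), GABA receptor genes 0.02 (0.827), voltage-gated ion channel genes 0.02 (0.522; mean −0.00), axon guidance and adhesion genes 0.01 (0.260) and presynaptic vesicle genes 0.05 (0.0902). Genes named in earlier work on Mecp2 mutants had a median of 0.02 (camera adjusted p = 0.252). Metabolic and housekeeping lists gave 0.03 for nuclear oxidative phosphorylation genes (camera adjusted p = 0.0644), 0.02 for ribosomal protein genes (0.469), −0.02 for cholesterol synthesis (0.957), 0.04 for heat shock genes (0.0644) and 0.01 for nuclear long noncoding RNAs (0.707). Glial and immune lists gave 0.10 for myelin genes (camera adjusted p = 0.669), −0.02 for reactive astrocyte genes (0.993; mean 0.06, test up), 0.02 for homeostatic microglial genes (0.707), 0.10 for activated microglial genes (0.0773) and 0.08 for interferon response genes (0.741). Among cell type markers, relay markers lay at 0.02 (camera adjusted p = 0.535; mean −0.02), inhibitory markers at 0.02 (0.957; mean −0.03), cortical or hippocampal markers at 0.04 (0.522), oligodendrocyte markers at 0.09 (0.522) and newly formed oligodendrocyte markers at 0.03 (0.522). Precursor markers lay at 0.10 (camera adjusted p = 0.694; mean −0.00), microglial markers at −0.01 (0.469; mean 0.12, test up), macrophage markers at −0.12 (0.669) and mural markers at 0.36 (0.0944).

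Long genes, whose expression is reported to rise when MeCP2 is lost, did not differ from short genes in relay neurons. The 2655 genes of at least 100 kb had a median log2 fold change of 0.00695 and the others −0.00482, a difference of 0.0118 (camera p = 0.239; p = 0.603 with an estimated correlation). By library, long minus short was 0.00211 in QKI B and 0.0218 in QKI D relative to the WT mean, while WT C differed from WT A by −0.0568, more than the genotypes differed. Leaving out WT C turned the difference to −0.0144 (camera p = 0.739), and leaving out WT A raised it to 0.0431 (camera p = 0.0298; p = 0.266 with an estimated correlation). Differences elsewhere were 0.00813 in inhibitory neurons, −0.0222 in astrocytes, −0.00313 in oligodendrocytes, −0.0244 in precursors, −0.0171 in microglia and 0.0529 in endothelial cells, with camera p between 0.0763 and 0.999.

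Inhibitory neurons showed no gene past the test. The class joined clusters 2, 7 and 13, and cluster 7 scored next highest for habenular neurons (1.46 against 2.06). Whether all nuclei of the class were interneurons of the dLGN was not tested. The cell adhesion gene Sdk1, which guides synaptic layering in the retina, measured 250 ± 7.36 CPM in WT and 378 ± 11.4 in QKI (log2 fold change 0.60, SE 0.12), and Ankrd31 54.0 ± 7.31 and 27.8 ± 0.271 CPM (−0.96, SE 0.18). The predicted genes Gm12002 (0.77, SE 0.19) and Gm47471 (−1.01, SE 0.24) came next. The edgeR quasi-likelihood test called 0 of 12637 genes, 496 had an unadjusted p under 0.05, DESeq2 called 0 with 61 under 0.05, and the lowest Benjamini-Hochberg adjusted p was 0.435, for Ankrd31. None of 29 lists passed camera: immediate early genes had a median of −0.17 with 2 of 10 positive (camera adjusted p = 0.201), late response genes 0.02 (0.849; mean −0.03), refinement genes 0.00 (0.849) and MeCP2 partners −0.03 (0.849). Adjusted over the list alone, 2 genes passed: the immediate early gene Fos at −1.56 (adjusted p = 0.0321) and the potassium channel Kcnq5 at 0.48 (adjusted p = 0.0415), against 0 over all genes tested. Fos measured 24.3, 8.82, 6.72 and 4.46 CPM in WT A, WT C, QKI B and QKI D, so WT A carried much of its difference. Mitochondrially encoded genes again stood apart in QKI D, with per-library medians of −0.19, 0.19, −0.22 and 0.54. The test called 57, 20, 5 and 5 inhibitory genes without WT A, WT C, QKI B and QKI D, and 9 with no low-count filter.

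Astrocytes, which take up glutamate at synapses, likewise showed no gene past the test. Slc38a1, a neutral amino acid transporter, came nearest, at 59.9 ± 1.98 CPM in WT and 107 ± 4.60 in QKI (log2 fold change 0.84, SE 0.14; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.105). The protease inhibitor A2m (0.84, SE 0.21), the transcription factor Foxk1 (−0.75, SE 0.18) and the predicted gene Gm34086 (−0.65, SE 0.17) followed. Of 12783 astrocyte genes the edgeR quasi-likelihood test called 0, 609 had an unadjusted p under 0.05, and DESeq2 called 0, with 39 under 0.05. Astrocyte genes called without WT A, WT C, QKI B and QKI D numbered 7, 205, 15 and 2, and 1 with no low-count filter.

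As groups, 8 of 30 lists rose in QKI astrocytes. Presynaptic vesicle genes (median 0.16, 21 of 28 positive, camera adjusted p = 0.00351) and voltage-gated ion channel genes (0.18, 28 of 36, 0.00131) were among them, with Syn1 at 0.57, Dnm1 at 0.47, Kcnq2 at 0.64 and Scn1b at 0.61, genes best known from neurons. With an estimated correlation p = 0.236 and p = 0.271. Late response genes rose (0.15, 13 of 18, camera adjusted p = 0.0256), with Rasgrp1 at 0.54 and Scg2 at 0.50, as did nuclear long noncoding RNAs (0.24, 6 of 7, 0.0170), with Snhg11 at 0.51. Their p with an estimated correlation was p = 0.0997 and p = 0.154. Ribosomal protein genes (0.20, 55 of 75, camera adjusted p = 0.00116), nuclear oxidative phosphorylation genes (0.07, 64 of 90, 0.0222), mitochondrially encoded genes (0.34, 12 of 13, 0.00351) and endothelial markers (0.51, 7 of 7, 0.00380) rose too, with Rpl8 at 0.43, Uqcr11 at 0.70, mt-Nd5 at 0.73 and Ly6c1 at 0.87. For these 4 lists an estimated correlation gave p = 0.234, p = 0.0617, p = 0.388 and p = 0.159. Per library the mitochondrial medians were −0.04, 0.04, −0.13 and 0.72 and the endothelial ones 0.04, −0.04, 0.08 and 0.68. Adjusted over the list alone, 9 gene and list pairs passed, among them Rasgrp1, Scn1b, Snhg11, the ligand Cx3cl1 (0.59, adjusted p = 0.0326) and the opsin Opn3 (1.14), against 0 over all genes tested. Per library Cx3cl1 lay at 55.1, 54.1, 69.0 and 94.6 CPM, highest in QKI D, and Snhg11 at 330, 477, 538 and 608, lowest in WT A. Without WT A all 8 list calls were lost, without QKI D 7 were lost and the mitochondrial list turned to −0.14, and without WT C or QKI B 3 and 2 were lost.

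Oligodendrocytes, the cells that make myelin, showed no gene past the test. Hspa5, the main chaperone of the endoplasmic reticulum, measured 30.6 ± 7.43 CPM in WT and 56.6 ± 5.86 in QKI (log2 fold change 0.90, SE 0.18; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.345). Aph1c, a subunit of gamma-secretase, lay at 0.903 and 5.79 CPM (2.54, SE 0.56), while the transporter Abca8b (−0.63, SE 0.15) and Uprt (−1.65, SE 0.42) were lower in QKI. The edgeR quasi-likelihood test called 0 of 12563 genes, 470 had an unadjusted p under 0.05, and DESeq2 called 0, with 31 under 0.05. Oligodendrocyte genes called without WT A, WT C, QKI B and QKI D numbered 7, 151, 3 and 0, and 1 with no low-count filter.

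In oligodendrocytes 12 of 27 lists rose in QKI. Heat shock genes rose with every member positive (median 0.17, 11 of 11, camera adjusted p = 9.93e-05; p = 0.124 with an estimated correlation), Hspa5 at 0.90 and Hsph1 at 0.34 among them. Genes of astrocytes rose, both as markers (0.57, 6 of 8, camera adjusted p = 0.000478) and as perisynaptic genes (0.35, 12 of 15, 0.000246), with Slc1a2 at 0.59, Sparc at 0.60 and Ntsr2 at 0.85. At an estimated correlation p = 0.162 and p = 0.232. Activity-regulated lists rose as well: late response genes (0.35, 13 of 15, camera adjusted p = 0.000367; p = 0.0483 with an estimated correlation, which adjusted to p = 0.744 and did not pass), with Vgf at 0.50 and Rasgrp1 at 0.48, and immediate early genes (0.33, 5 of 6, camera adjusted p = 0.0400; p = 0.136 with an estimated correlation), with Dusp1 at 0.57 and Jun at 0.47. Neuronal lists followed, namely glutamate receptor genes (0.12, 21 of 33, camera adjusted p = 0.00670), GABA receptor genes (0.18, 14 of 14, 0.00724), presynaptic vesicle genes (0.13, 23 of 27, 0.00829) and relay markers (0.11, 9 of 12, 0.0400), with Gria3 at 0.50, Gabrb3 at 0.37, Cplx1 at 0.38 and Prkcd at 0.36. An estimated correlation gave p = 0.316, p = 0.327, p = 0.262 and p = 0.330 for those 4. Genes named in earlier Mecp2 work (0.28, 13 of 16, camera adjusted p = 0.0400), mitochondrially encoded genes (0.32, 13 of 13, 0.0217) and endothelial markers (0.37, 7 of 7, 0.0289) completed the set, with Id3 at 1.09, Opn3 at 0.75 and Flt1 at 0.54. Of these 3 the estimated correlation gave p = 0.320, p = 0.498 and p = 0.376. Per library the mitochondrial medians were 0.04, −0.04, −0.23 and 0.71 and the endothelial ones 0.01, −0.01, −0.18 and 0.71. Adjusted over the list alone, 6 gene and list pairs passed, with Hspa5 (adjusted p = 0.000302), Id3, Slc1a2, Sparc and Sparcl1 (0.48), against 0 over all genes tested. QKI D carried much of the difference in Id3 (7.67, 8.47, 11.0 and 21.8 CPM), Sparc (37.5, 43.9, 48.1 and 73.2) and Sparcl1 (54.3, 53.5, 60.4 and 88.0). Without WT A, WT C and QKI B 8, 5 and 2 of the 12 list calls were lost, without QKI D 8 were lost and the mitochondrial and endothelial lists turned to −0.23 and −0.18, and with no low-count filter 4 were lost.

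Oligodendrocyte precursors, the dividing cells that give rise to oligodendrocytes, showed no gene past the test. Ptgds, which makes prostaglandin D2 and is abundant in meningeal fibroblasts and mature oligodendrocytes, measured 2.78 ± 0.577 CPM in WT and 15.7 ± 4.81 in QKI (log2 fold change 2.48, SE 0.61). Mrps31, a protein of the mitochondrial ribosome, lay at 1.70 (SE 0.46), Mphosph9 at −0.66 (SE 0.17) and Thoc5, of the complex that exports messenger RNA, at −1.03 (SE 0.29). Of 11156 precursor genes the edgeR quasi-likelihood test called 0, 540 had an unadjusted p under 0.05, DESeq2 called 0 with 21 under 0.05, and the lowest Benjamini-Hochberg adjusted p was 0.468. Without WT A, WT C, QKI B or QKI D the test called 3, 10, 12 and 0 precursor genes.

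Among lists, 8 of 26 rose in QKI precursors. Myelin genes (median 0.28, 9 of 12, camera adjusted p = 0.0272) and oligodendrocyte markers (0.31, 9 of 9, 0.00753) rose, with Mal at 0.68 and Mog at 0.59, as did heat shock genes (0.28, 8 of 10, 0.00753), with Dnajb1 at 0.88 and Hspa5 at 0.48. These 3 lists had p = 0.396, p = 0.363 and p = 0.0752 with an estimated correlation. Mitochondrially encoded genes (0.46, 13 of 13, camera adjusted p = 0.000855) and endothelial markers (0.86, 5 of 5, 0.00483) rose the furthest, with mt-Nd4l at 1.10 and Flt1 at 0.89; p = 0.331 and p = 0.211 with an estimated correlation. Presynaptic vesicle genes (0.06, 19 of 28, camera adjusted p = 0.0215), nuclear oxidative phosphorylation genes (0.15, 51 of 78, 0.0215) and perisynaptic astrocyte genes (0.22, 10 of 14, 0.0197) rose as well, with Vamp1 at 0.76, Atp5b at 0.49, Ndufv2 at −0.66 and Glul at 0.58. With an estimated correlation they had p = 0.292, p = 0.234 and p = 0.247. Per library the mitochondrial medians were −0.06, 0.06, −0.14 and 0.83 and the endothelial ones 0.14, −0.14, 0.16 and 1.17. Adjusted over the list alone, 10 gene and list pairs passed, among them Nrn1, a late response gene (0.74, adjusted p = 0.00722), Ldlr, the receptor for low-density lipoprotein (−0.86, adjusted p = 0.0171), Mal, Apoe (0.59) and Flt1, against 0 over all genes tested. Here too QKI D stood furthest out, in Mal (57.0, 75.0, 78.2 and 123 CPM), Apoe (51.5, 59.0, 61.0 and 99.7), Flt1 (21.4, 17.6, 27.7 and 45.2) and Ldlr (52.3, 49.5, 35.3 and 22.2). Without WT A all 8 list calls were lost and without WT C 1, and without QKI D 5 were lost and the myelin, mitochondrial and oligodendrocyte lists turned to −0.18, −0.13 and −0.23.

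Microglia, the immune cells that engulf synapses during refinement, showed no gene past the test. Atp1a2, a sodium pump subunit best known from astrocytes, measured 117 ± 38.1 CPM in WT and 250 ± 33.2 in QKI (log2 fold change 1.18, SE 0.25), and Syne1 lay at 1.00 (SE 0.29). The lipid phosphatase Plpp1 (−1.45, SE 0.36) and the nuclear pore gene Nup160 (−1.71, SE 0.44) were lower in QKI. Of 6953 microglial genes the edgeR quasi-likelihood test called 0, 340 had an unadjusted p under 0.05, DESeq2 called 0 with 24 under 0.05, and the lowest Benjamini-Hochberg adjusted p was 0.411, for Atp1a2. Without WT A, WT C, QKI B or QKI D the test called 0, 8, 2 and 0 microglial genes, and 4 with no low-count filter.

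Homeostatic microglial genes fell as a list in QKI microglia (median −0.13, 2 of 12 positive, camera adjusted p = 0.0387; p = 0.376 with an estimated correlation), with P2ry12 at −0.36, Sall1 at −0.42, Siglech at −0.22 and Olfml3 at −0.51. The other 11 of the 12 passing lists rose, out of 25 tested, and most of these hold genes best known from other cells. Relay markers (0.29, 10 of 11, camera adjusted p = 0.00161), perisynaptic astrocyte genes (0.33, 11 of 12, 0.000467), astrocyte markers (0.30, 5 of 5, 0.0197), endothelial markers (0.37, 5 of 6, 0.0257) and myelin genes (0.35, 9 of 10, 0.00161) were among them, with Rora at 0.47, Gja1 at 1.07, Ly6c1 at 1.31 and Ugt8a at 1.07. For those 5 an estimated correlation gave p = 0.209, p = 0.0885, p = 0.145, p = 0.167 and p = 0.296. Synaptic lists rose as well, namely glutamate receptor (0.21, 19 of 26, camera adjusted p = 0.0387), ion channel (0.22, 19 of 25, 0.0106) and presynaptic vesicle genes (0.22, 19 of 24, 0.00686), with Kcnd2 at 0.65 and Cplx1 at 0.55. An estimated correlation left them at p = 0.421, p = 0.326 and p = 0.353. So did mitochondrially encoded genes (0.51, 12 of 12, camera adjusted p = 4.04e-06), nuclear oxidative phosphorylation genes (0.14, 34 of 55, 0.0357) and nuclear long noncoding RNAs (0.35, 3 of 5, 0.0303), with mt-Nd3 at 0.67 and Snhg11 at 0.53. Here p = 0.238, p = 0.107 and p = 0.335 with an estimated correlation. The mitochondrial medians per library were 0.04, −0.04, −0.09 and 0.89, and the median mitochondrial share of UMIs in microglia was 0.388%, 0.358%, 0.343% and 0.666%. Adjusted over the list alone, 3 genes passed, Snhg11, Ly6c1 and Apoe, a lipid carrier raised in activated microglia (1.01), against 0 over all genes tested. Microglial Apoe measured 84.1, 64.5, 113 and 188 CPM, highest in QKI D, and Snhg11 635, 923, 1020 and 1196, lowest in WT A. Without QKI D 10 of the 12 list calls were lost and the myelin and mitochondrial lists turned (−0.14 and −0.14), without WT A 9 were lost and the homeostatic list turned by its test at a median of −0.06, and without WT C, or with no low-count filter, 2 and 3 were lost.

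Endothelial cells, which line blood vessels, showed no gene past the test and the least precision. The libraries filled their clusters 11 and 18 unevenly. Cluster 18 (median 4293 UMIs), which also carried mural markers, held 128, 118, 190 and 222 nuclei of WT A, WT C, QKI B and QKI D. Cluster 11 (median 1541 UMIs) held 67, 170, 164 and 264. In the fit without cluster 18, added after the data had been seen, edgeR called 0 of 6076 genes, with 201 at an unadjusted p under 0.05. Ifitm3, an interferon-induced antiviral protein, measured 51.4 ± 6.27 CPM in WT and 25.1 ± 0.206 in QKI (log2 fold change −1.02, SE 0.23), and Tpk1, which makes the cofactor form of thiamine, lay at −0.57 (SE 0.15). Sdhaf3, an assembly factor of succinate dehydrogenase (1.51, SE 0.39), and Coro6 (1.28, SE 0.35) were higher in QKI. Of 11529 endothelial genes the edgeR quasi-likelihood test called 0, 186 had an unadjusted p under 0.05, DESeq2 called 0 with 3 under 0.05, and Ifitm3 passed when adjusted over the list alone (adjusted p = 0.0465), against 0 over all genes tested. Leaving out WT C gave 90 endothelial genes, and leaving out each other library 0.

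In endothelial cells 9 lists rose and 2 fell in QKI, of 30 tested. Ribosomal protein genes fell (median −0.21, 14 of 69 positive, camera adjusted p = 2.32e-06), with Rpl14 at −0.51 and Rpl21 at −0.41, as did immediate early genes (−0.27, 3 of 11 positive, 0.0104), with Maff at −0.80 and Junb at −0.60. Their p was p = 0.234 and p = 0.235 with an estimated correlation. Neuronal lists rose, with presynaptic vesicle genes (0.44, 24 of 27, camera adjusted p = 2.32e-06), ion channel genes (0.38, 33 of 37, 7.37e-05), glutamate receptor genes (0.37, 28 of 32, 0.00170) and GABA receptor genes (0.46, 13 of 14, 0.00253), Vamp1 at 0.59 among them. An estimated correlation gave p = 0.244, p = 0.402, p = 0.446 and p = 0.411 for those 4. Myelin genes (0.35, 13 of 14, camera adjusted p = 0.00639), oligodendrocyte markers (0.31, 10 of 11, 0.0406), mitochondrially encoded genes (0.21, 13 of 13, 0.0145), late response genes (0.29, 12 of 16, 0.0406) and cholesterol synthesis genes (0.19, 13 of 17, 0.0352) rose too, with Idi1 at 0.96 and Hmgcs1 at 0.41. For those 5 an estimated correlation gave p = 0.394, p = 0.492, p = 0.415, p = 0.171 and p = 0.366. The 4 neuronal lists differed more between C and D and A and B, a grouping chosen after the results had been seen. It sets a WT and a QKI library on each side. Presynaptic, ion channel, glutamate receptor and GABA receptor medians were 0.778, 1.036, 1.245 and 1.043 higher in C and D. None passed with an estimated correlation (lowest adjusted p = 0.480). Their rise in QKI is thus not taken as a difference between genotypes. Per library the mitochondrial medians were 0.03, −0.03, −0.04 and 0.49, so QKI D again lay apart. Without WT A 5 of the 11 list calls were lost and 5 turned, glutamate receptor genes to −0.32, ion channel genes to −0.26, oligodendrocyte markers to −0.26 and GABA receptor genes to −0.03, with myelin genes turned by their test at 0.01. Without QKI D 9 were lost and mitochondrial genes turned to −0.04, and without WT C, or with no low-count filter, 1 was lost.

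Over all nuclei together, a profile that also moves with the shares of classes, no gene passed the test. Ptgds measured 13.8 CPM in WT and 21.1 in QKI (log2 fold change 0.61, SE 0.11), beside the higher share of fibroblasts in QKI libraries given above, and the predicted gene Gm43507 lay at 0.61 (SE 0.13). Lrrc40 (−0.32, SE 0.07) and Igsf21 (−0.26, SE 0.07) were lower in QKI here as in relay neurons, which supply many of these nuclei. The edgeR quasi-likelihood test called 0 of 19314 genes, 347 had an unadjusted p under 0.05, and DESeq2 called 0, with 92 under 0.05. The genes called without QKI D, here as in relay neurons, were Ccdc172, 1810007D17Rik and Pnlip. They were transcribed almost wholly in QKI B, as described below.

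Of 34 lists, 12 rose in QKI over all nuclei. Synapse refinement genes rose (median 0.07, 14 of 21, camera adjusted p = 0.0168; p = 0.358 with an estimated correlation), with the complement gene C1qa at 0.55 and the phagocytic receptor Mertk at 0.28. Astrocyte lists rose, as markers (0.19, 11 of 11, camera adjusted p = 1.24e-08), perisynaptic genes (0.19, 17 of 20, 4.14e-08) and reactive genes (0.04, 10 of 12, 0.0168), with Gjb6 at 0.38, Ntsr2 at 0.31 and C4b at 0.91. Respective p with an estimated correlation were p = 0.122, p = 0.150 and p = 0.131. Other cell type markers rose, namely those of fibroblasts (0.35, 5 of 6, camera adjusted p = 3.32e-05), inhibitory neurons (0.20, 10 of 12, 0.000449), newly formed oligodendrocytes (0.10, 7 of 7, 0.0168) and endothelial cells (0.25, 8 of 8, 0.00500), with Dcn at 0.63, Gad2 at 0.27, Enpp6 at 0.22 and Ly6c1 at 0.39. These had p = 0.0612, p = 0.133, p = 0.309 and p = 0.346 with an estimated correlation. Heat shock genes (0.11, 13 of 14, camera adjusted p = 4.72e-05), mitochondrially encoded genes (0.37, 13 of 13, 3.32e-05), nuclear oxidative phosphorylation genes (0.06, 72 of 94, 0.00179) and ribosomal protein genes (0.06, 56 of 79, 0.0350) rose as well, with Hspa5 at 0.31. They had p = 0.0552, p = 0.302, p = 0.336 and p = 0.349 with an estimated correlation. Per library the mitochondrial medians were −0.02, 0.02, −0.14 and 0.75. Without WT A, WT C, QKI B and QKI D 4, 5, 2 and 6 of the 12 list calls were lost, the refinement and mitochondrial lists turned to −0.01 and −0.15 without QKI D, and endothelial markers turned to −0.09 without WT C.

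Relay neurons and microglia differed in how a single gene changed with genotype. Mgat5b, a glycosyltransferase expressed in brain, lay at 5.80, 4.96, 49.1 and 49.5 CPM in microglia of WT A, WT C, QKI B and QKI D (log2 fold change 3.07, SE 0.72), and at 183, 163, 175 and 161 CPM in relay neurons (−0.04). The interaction was −3.23 (SE 0.68; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0366). Within microglia alone the edgeR quasi-likelihood test gave Mgat5b a Benjamini-Hochberg adjusted p = 0.660, and its mean count of 8.75 per library lies below the minimum for naming a gene. With no low-count filter Mgat5b was among the microglial genes that test called. Each comparison of relay neurons with another class was adjusted on its own, not over all of them together. No gene passed the interaction of relay neurons with inhibitory neurons, astrocytes, oligodendrocytes, precursors or endothelial cells in edgeR, where 783, 663, 526, 630 and 336 genes had an unadjusted p under 0.05. DESeq2 was not run for the interaction.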

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

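No test in this part was chosen after the result was seen. Among the comparisons of relay neurons with the other classes, a lone gene passed: Mgat5b, with an interaction of −3.23 on the log2 scale (SE 0.68; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0366, and 0.0413 with RLE scaling). What drew attention was a difference between genotypes in microglia, 5.80 and 4.96 CPM in WT against 49.1 and 49.5 CPM in QKI, beside 183, 163, 175 and 161 CPM in relay neurons. The p-values were adjusted within each comparison of classes, not over all comparisons together. The microglial values rest on a mean count of 8.75 per library, and no explanation for them was tested.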

How the results depend on the processing

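No test in this part was chosen after the result was seen, apart from the fits with a term for A and B against C and D and those without the shallowest relay cluster or the mural-marked endothelial cluster. No paired analysis was possible because WT and QKI libraries share no replicate letter and the labels name no pairs; the term for A and B against C and D sets a WT and a QKI library on each side, but was taken from the data. Of the comparisons between genotypes, 88 alternative results kept their direction and their side of the threshold, 31 gained calls, 4 lost them, 2 moved by over 1.5 times and 1 turned. The named genes kept theirs in 398 alternatives, gained a call in 44 and turned in 0, and Mecp2 in relay neurons ranged from −0.08 (without QKI D) to −0.02 (without QKI B). The lists kept their calls in 325 alternatives, lost them in 127 and turned in 21; the cause was not tested.

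Leaving out a library leaves 3, and the lone one is assumed to vary like the other group. Genes called by edgeR when WT A, WT C, QKI B or QKI D was left out numbered 76, 184, 0 and 3 in relay neurons, 57, 20, 5 and 5 in inhibitory neurons, 7, 205, 15 and 2 in astrocytes, 7, 151, 3 and 0 in oligodendrocytes, 3, 10, 12 and 0 in precursors, 0, 8, 2 and 0 in microglia, 0, 90, 0 and 0 in endothelial cells, and 0, 0, 0 and 3 in all nuclei. With no low-count filter 9 inhibitory, 1 astrocyte, 1 oligodendrocyte and 4 microglial genes were called. The term for A and B against C and D gave 16 relay, 7 inhibitory, 1 astrocyte, 2 oligodendrocyte and 1 microglial gene; simulated data with no change gave 16, 4, 0, 12 and 1. With the same term A and D against B and C, a grouping unrelated to genotype, called 24, 1, 10, 55 and 1. The astrocyte gene was Slc38a1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000546 with the term, 0.105 without). DESeq2 called 0 in every class.

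Of list and class pairs, 67 passed camera, 0 passed with an estimated correlation and 0 with fry, 70 passed with no low-count filter, 88 with the split term, 74 without the shallowest relay cluster, and 28 to 108 with a library left out. For the fit without the shallowest relay cluster, relay neurons alone were refitted, so every call gained over the 67 was a relay list. Lists that turned had these lowest and highest medians with a library left out. Mitochondrially encoded genes: −0.16 to 0.60 in relay neurons, −0.14 to 0.72 in astrocytes, −0.23 to 0.71 in oligodendrocytes, −0.13 to 0.83 in precursors, −0.14 to 0.92 in microglia, −0.041 to 0.48 in endothelial cells and −0.15 to 0.75 in all nuclei. Endothelial markers: −0.18 to 0.76 in oligodendrocytes and −0.0891 to 0.64 in all nuclei. Relay neurons: perisynaptic genes −0.075 to 0.56, astrocyte markers −0.12 to 0.66. Precursors: myelin genes −0.18 to 0.66, oligodendrocyte markers −0.23 to 0.77. Microglia: myelin genes −0.14 to 0.64, homeostatic genes −0.26 to −0.0616. Endothelial cells: glutamate receptor genes −0.32 to 1.56, GABA receptor genes −0.0272 to 1.46, ion channel genes −0.26 to 1.56, myelin genes 0.0127 to 1.26, oligodendrocyte markers −0.26 to 1.31. Refinement genes in all nuclei: −0.0085 to 0.12. The difference of long from short genes ran from −0.0144 to 0.0431. Shares of fibroblasts and mural cells moved to 0.0953 and −0.0385 points at 1000 genes per nucleus. That of unnamed nuclei moved from −0.336 to −1.16 at resolution 2.0, within the WT standard deviation of 0.861. Each of these moves exceeded the spread between libraries when pooled over both genotypes. At 1000 genes the other shares moved within it: relay neurons from −4.58 to −1.22 points, astrocytes from 2.38 to 0.194 and inhibitory neurons from 0.394 to 1.07, while precursors (0.143 to −0.769) and newly formed oligodendrocytes (0.333 to −0.0691) turned sign. The cause was not tested. Depth limited how many genes could be tested, 6953 in microglia against 17124 in relay neurons. Recovery of 2-fold changes in the simulation was lowest in endothelial cells (14%), whose libraries also varied most (biological coefficient of variation 0.209, against 0.0727 in relay neurons).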

Other observations

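The grouping of A and B against C and D, the fit of newly formed oligodendrocytes, and the tests marked below as later were chosen after the results had been seen; the genes and cell groups in this part were picked by looking through the values. Some immediate early genes differed between libraries of the same genotype. In relay neurons the immediate early gene Fos measured 11.5, 4.62, 9.78 and 3.44 CPM in WT A, WT C, QKI B and QKI D (log2 fold change −1.41 for C and D against A and B), with Npas4 at −1.08 and Nr4a1 at −0.53. As a list, immediate early genes had a median of −0.70 with 12 of 17 members negative (camera adjusted p = 9.81e-17). That call was lost with an estimated correlation (adjusted p = 0.370), and late response genes, the other list of activity-induced genes, did not pass (−0.12, camera adjusted p = 0.0726; adjusted p = 0.532 with an estimated correlation). Myelin genes went the other way in the same nuclei (0.67, 0 of 16 negative, camera adjusted p = 7.33e-33; adjusted p = 0.370 with an estimated correlation, so lost as well), with Mal at 0.78 and Cldn11 at 0.65. Mitochondrially encoded genes (0.55, 0 of 13 negative), astrocyte markers (0.52, 0 of 11), microglial markers (0.51, 0 of 10) and precursor markers (0.32, 0 of 8) moved up with them, and passed camera but not the estimated correlation (adjusted p = 0.442, 0.501, 0.501 and 0.501). Fkbp5, a member of the list of genes named in earlier work on Mecp2 mutants, and Zbtb16, in no list, were picked by eye. Over all nuclei both were lowest in WT A. Fkbp5 measured 19.8, 67.9, 46.1 and 59.6 CPM in WT A, WT C, QKI B and QKI D, and Zbtb16 49.0, 136, 109 and 158 CPM.

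Newly formed oligodendrocytes showed no gene past the edgeR test (0 of 10784, 348 at an unadjusted p under 0.05), with Sult4a1 at 1.05, Gspt2 at 1.67, Mertk at 1.17 and Neat1 at −0.69; DESeq2 was not run for this class. At resolution 2.0 a cluster of 39 astrocytes with interferon-induced genes (Oasl2, Rsad2, Mx1, Trim30a) held 3, 1, 2 and 33 nuclei of WT A, WT C, QKI B and QKI D. Dividing precursors, marked by Top2a and Mki67, formed a cluster with 20, 10, 15 and 24 nuclei.

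In relay neurons A and B against C and D called 146 genes (80 higher and 66 lower in C and D). The genotypes called 0 in edgeR (396 at an unadjusted p under 0.05) and 0 in DESeq2. Elsewhere the grouping called 2 inhibitory, 5 astrocyte, 5 oligodendrocyte, 23 precursor, 1 microglial and 233 endothelial genes, and 0 over all nuclei. After thinning to equal totals 136 genes were called, 121 of them among the 146, which met the bound set beforehand against unequal totals as the cause. The totals were already close (20482667, 18825117, 23136566 and 22424602 UMIs in WT A, WT C, QKI B and QKI D), so thinning could change little. It leaves depth per nucleus, with medians of 8834, 4264, 5660 and 5883 UMIs, unaddressed. The shallowest relay cluster may account for part: without it 45 genes were called, 40 of them shared, though fewer nuclei also lower the count. A later test of free oligodendrocyte RNA could not decide for the called genes. Of those higher in C and D, 30.0% (24 of 80) had at least 2 times their relay level in oligodendrocytes. Oligodendrocyte markers as a list lay higher in C and D in relay neurons (median log2 difference 0.78), inhibitory neurons (0.81) and astrocytes (0.60). They did so in precursors (0.55) and microglia (0.64) too, but not in oligodendrocytes (−0.03). Free oligodendrocyte RNA would give that pattern in those markers, though none of these list calls held with an estimated correlation. Differences between the pools of mice, such as activity before collection, remain open, since the labels name no batch.

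Mitochondrially encoded genes and endothelial markers passed camera as higher in QKI in several classes, though not with an estimated correlation. Neither list passed in inhibitory neurons, and endothelial markers did not pass in endothelial cells. Later, 3 tests weighed what could lie behind the rise. Of mitochondrial genes the QKI B median lay at or below the WT mean in 8 of 8 profiles, so QKI D alone carried that difference; the per-library medians had prompted this test, so it describes the pattern and does not explain it. Endothelial markers were mixed: in oligodendrocytes QKI D alone lay above the WT mean (0.71, against −0.18 in QKI B), whereas QKI B lay above it too in relay neurons (0.20), precursors (0.16), microglia (0.31) and astrocytes (0.08), and QKI D lay below it in endothelial cells (−0.01) and inhibitory neurons (−0.15). Cytoplasmic RNA left in QKI D was left undecided, with 6 of 8 profiles meeting its prediction. Free endothelial RNA met its prediction in 6 of 6 classes, but the inhibitory median of 0.02 came with 4 of 7 members positive, a mean of −0.10 and library medians of −0.11 (QKI B) and −0.15 (QKI D), so this too was left undecided.

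A stretch of chromosome 19 was transcribed almost wholly in QKI B. Over all nuclei Ccdc172 (58511993–58553085), 1810007D17Rik (58606329–58629753) and Pnlip (58652498–58681788) measured 43.4, 32.6 and 4.31 CPM there, 251, 160 and 84.9 times the other libraries. The neighbour Gfra1 lay at 98.7, 84.6, 120 and 94.6 CPM in WT A, WT C, QKI B and QKI D. By class, QKI B was highest for Gfra1 in relay neurons (82.7, 79.4, 115 and 89.7), inhibitory neurons (68.6, 51.4, 94.9 and 63.7), astrocytes (18.2, 17.2, 27.4 and 13.9) and precursors (337, 296, 373 and 288). It was not highest in oligodendrocytes, microglia or endothelial cells. Whether Gfra1 shares in the pattern was not tested. Free RNA of a single cell type could make Ccdc172 uneven. Its levels in QKI B spanned 115-fold, from 95.3 CPM in inhibitory neurons to 0.831 (1 UMI) in endothelial cells. That met the bound of 10 written beforehand for this explanation. Expression in several classes meets the bound too, so it cannot tell them apart. Later tests left free RNA of inhibitory neurons undecided over the other classes together. Astrocytes held 5.65 times the level of precursors (interval 2.63 to 14.4), but that gap was picked from levels already seen. The mean share of the inhibitory level in the 6 other classes was 0.176, against at most 0.0917 among 10 inhibitory markers. That fell short of the 2 times set to exclude it, though in relay neurons alone the share was 0.534 against at most 0.0208. Relay nuclei of QKI B carried both Ccdc172 and 1810007D17Rik 3.33 times as often as chance (interval 3.09 to 3.55; 375 nuclei, where 680 and 570 of 3874 carried each), against a median of 1.01 (0.866 to 1.16) in 500 control pairs. Transcription in some of the 3 pooled mice could give this. So could other uneven transcription of the stretch among relay nuclei, which the test does not separate. In relay neurons 1810007D17Rik and Pnlip lay at 38.8 and 5.06 CPM, against 65.7 and 7.88 in inhibitory neurons. With the Ccdc172 shares, this argues against free RNA of inhibitory neurons as the source in relay neurons of QKI B. For other classes or another source free RNA is not excluded, and what caused the pattern was not tested.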
